A study of Rattus norvegicus with 16 samples.

How the data were processed

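RNA from 16 tissue samples of the rat initial segment was hybridised to Affymetrix rat arrays, 1 array per sample, 4 each for sham and for 6, 12 and 18 h after efferent duct ligation. Per the labels' protocols, the most proximal piece of the segment was dissected, total RNA was purified over columns with a DNase step, and biotin-labelled RNA was hybridised. The values used are those of the deposited value table, 1 log2 value per probe set and array. They were made with GCRMA, a background correction by probe sequence followed by quantile normalization and summary, per the submitters' processing notes; its version is not given in the sources used here. The values ran from 2.22 to 15.1. Scanner files were not analysed here.

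The table held 31099 probe sets, of which 57 control probe sets were left out of the tests, leaving 31042. The platform annotation of 2016 gave 20826 of these 1 gene symbol, 436 several and 9780 none. Symbols were looked up by Entrez ID in a gene table of the rat assembly GRCr8, where 20758 were found and 68 were not, and 0 symbols changed. A gene was represented by its probe set with the highest mean over all 16 arrays. No genome coordinates were used. Srd5a1, chosen in advance, had no matched probe set.

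A probe set was tested if it lay at or above 5 on the log2 scale in at least 4 of the 16 arrays, which left 13410 probe sets (10869 with 1 symbol) and 8344 genes. Differences were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with the default prior) in 1 fit of the 4 group means over all 16 arrays, so that the groups shared 1 estimate of the spread. P-values were adjusted by the Benjamini-Hochberg method over the tested probe sets within each comparison, and a call is an adjusted p under 0.05. The 6 comparisons were each time against sham and each pair of times, and a moderated F-test took the 3 times against sham together. With 4 arrays in each group, each p-value measures the spread between these arrays. After the submitters' normalization, which brings medians together, medians of the tested probe sets were 7.51 to 7.62. Correlations between arrays were 0.882 to 0.986, with 0 pairs of identical arrays, and the hybridisation controls ran from 8.74 to 11.04.

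Gene lists (35 lists, 654 symbols, 570 of them matched) covered ERK output, immediate early genes, STAT targets, NFKB targets, the interferon response, pro-apoptotic, anti-apoptotic and p53 target genes, the unfolded protein response, initial segment genes, more distal caput genes, growth factors and receptors, androgen and glucocorticoid targets, the circadian clock, the cell cycle, cholesterol synthesis, glutathione and oxidative stress, hypoxia and glycolysis, transport, and injury and matrix remodelling, with reference genes and markers of 14 cell types. The anti-apoptotic list held Tnfrsf21, a death receptor gene. Members of the lists were counted over all tested probe sets and adjusted over the list alone. The 31 lists with at least 3 tested members were tested with limma's camera (preset correlation 0.01), adjusted over the lists, and again with an estimated correlation. Camera asks whether a list moved more than the other genes. Limma's fry was an alternative.

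Named genes followed a rule. Against sham it took the 8 largest rises and 8 largest falls among called genes whose 4 ligated arrays all lay beyond all 4 sham arrays, and between times the 4 largest each way, leaving out symbols that begin with LOC or RGD. From each list it took up to 4 called members or, where none was called, the member with the smallest p. Etv4, Etv5, Etv1, Dusp6, Spry4, Egr1, Ggt1, Srd5a1, Cst8, Socs3, Nfkbia and Bcl2l1 were always included, and 1 more gene chosen in advance is not reported here. Cst11 and Cst12, and Penk at 12 h, were chosen after their values were seen. The groups, comparisons, tests, lists, named gene rule and most alternatives were fixed before the data were examined.

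The alternatives fixed in advance were eBayes with a trend and robust prior, no minimum level, a stricter minimum of 7, arrays centred on their medians, quantile or cyclic loess normalization again, only the 2 groups compared, the replicate number as a block, arrayWeights (with statmod 1.5.0), probe sets averaged by gene symbol, a fold change of at least 2, an adjusted p under 0.01, fry or an estimated correlation for the lists, and each array left out in turn. Blocks for the array set and for replicates 1 and 2 against 3 and 4, and fits within each of these pairs, were added after the data were seen, because the arrays divided along the replicate numbers. The set was read from control transcripts and from the replicate number, not from the groups' outcome. With the arrays centred or normalized again, the median change of all tested probe sets stayed between -0.0154 and 0.0128 in the 6 comparisons.

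Whether replicate numbers pair the arrays was checked by correlating deviations from the group means. The lowest correlation between arrays of the same number was 0.276 for 6 h and 0.206 for 12 h against sham, 0.334 for 12 h and 6 h, 0.279 for 18 h and 12 h, and 0.388 for 18 h and 6 h. In these comparisons the number was treated as if it paired the arrays, and results with it as a block are given beside those without it. They cannot be read as paired by animal. The pairing rests on this check and not on the labels. For the same number the mean correlations were 0.311 to 0.439, and for different numbers in the same pair of replicates they were 0.288 to 0.384. For 12 h and 18 h against sham the different numbers correlated better (0.384 against 0.377 and 0.344 against 0.311). The check therefore cannot tell pairing from a divide between replicates 1 and 2 and replicates 3 and 4. As 1 side of each animal was ligated, ligated arrays of different times cannot share an animal, whatever their numbers. Between times the block therefore does not pair animals.

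The fit was tested on simulated data made from the 18 h and sham arrays over 13410 probe sets. It recovered 12 of 67 probe sets (17.9%) changed by 0.5 log2 units, 39 of 67 (58.2%) changed by 1 and 60 of 66 (90.9%) changed by 2, with 5 false calls among 116. Camera called a simulated list of 13 members moved by 0.5 (adjusted p = 8.05e-16) and 0 of the 30 others. The simulated probe sets and arrays varied independently. These simulations therefore cannot show how many false calls arise where list members vary together or replicates divide. For the comparisons that share the sham arrays, unchanged groups were simulated 20 times and the sham arrays were split 6 ways. Other splits of the arrays were fitted to see how many calls each gave, up to 100 splits drawn for the F-test.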

Results

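Gene expression was measured in the initial segment of the epididymis, the part nearest the testis, in adult male Sprague-Dawley rats after efferent duct ligation. The operation ties off the ducts that carry testicular fluid into the epididymis. Per the labels, 1 side of each animal was ligated and the other side was sham-operated, and tissue was taken 6, 12 or 18 h later. There were 4 groups of 4 arrays (sham, 6 h, 12 h and 18 h), 16 arrays in all. The 1 sham group served for every time, so changes with time apart from ligation were not measured. The labels call the replicates biological but do not say that a replicate number stands for an animal. Between 41.2% and 41.8% of the probe sets on each array lay at or above 5 on the log2 scale, and 31.2% to 33.0% lay within 0.01 of the lowest value, 2.22. The number of arrays limits the precision. The series title names the ERK, STAT and NFKB pathways and apoptosis, and each comparison with sham asked which of their genes had changed by that time. A change is a difference of group means in log2 units ± its SE, with n = 4 arrays in each group, and the adjusted p is limma's. A level under 5 was not told from background, so a change between such a group mean and a higher one bounds the true change from below, its SE is that of the measured values, and between 2 such means no change is measured. Sham means under 5 were those of Atf3 (2.35), Krt17 (2.42), Mmp7 (2.45), B3galt5 (2.69), Gpx2 (2.79), Fgg (2.90), Nags (2.95), Ccl2 (3.49), Fga (3.59), Ampd3 (3.85), Rasl10a (4.01), A2m (4.08), Chac1 (4.10), Myc (4.18), Isg15 (4.22), Cpne8 (4.40) and Slc7a11 (4.65), among other named genes. Falls to a ligated mean under 5 are lower bounds too, and those means are not all listed. A pair of values after a change gives it within replicates 1 and 2 and then within replicates 3 and 4. Values of a gene are those of the 1 probe set that represents it. Other tested probe sets of named genes called against sham numbered 6, 32 and 39 at 6, 12 and 18 h. All went the same way, but only 1, 16 and 24 of them were called.

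The arrays were put into 3 sets by replicate number and a control transcript. Replicates 1 and 2 of all 4 groups formed set 1. Replicates 3 and 4 of sham and 6 h formed set 2, in which a bacterial dap control transcript was measured at 7.10 to 7.93, and replicates 3 and 4 of 12 h and 18 h formed set 3, in which it was at the floor. With the group in the model, limma called 4954 of the 13410 tested probe sets (36.9%) between replicates 3 and 4 and replicates 1 and 2, 2452 higher and 2502 lower. Between sets 3 and 2 it called 10. Sets 2 and 3 share no group, so this count rests only on how changes with time differed between the pairs of replicates. It cannot show that the 2 sets are alike. Fibroblast markers were lower in replicates 3 and 4 by a median log2 difference of -1.38, with 12 of 13 called lower. Macrophage markers were lower too, with a median of -0.89 and 10 of 12 called lower. The median was -0.87 for the fat markers (2 of 5 called lower), -0.24 for smooth muscle (4 of 10 called lower), -0.03 for the endothelial markers (3 of 9 called lower) and -0.08 for the epithelial markers (2 of 13 called lower and 2 higher). Signs of array and RNA quality differed between the sets. The hybridisation controls had means of 9.79, 10.50 and 10.74 in sets 1, 2 and 3. The 3' minus 5' level of Gapdh was 0.191 to 0.293 in set 3, against -0.034 to 0.149 in set 1 and -0.098 to 0.073 in set 2, with means of 0.147 at 12 h, 0.127 at 18 h, 0.053 at 6 h and 0.020 in sham. That of beta-actin ordered the sets otherwise, with means of 1.41, 1.18 and 1.39 in sets 1, 2 and 3. Its means were 1.35 at 12 h, 1.44 at 18 h, 1.29 at 6 h and 1.31 in sham. Because every group holds 2 arrays on each side of this divide, counts within each side and counts with the set as a block (the set block) stand beside the pooled ones, with such values for some of the genes and lists. Of 434 results for named genes the set block ended the call of 54 and added 11. The set block can estimate 12 h or 18 h against sham or 6 h only through replicates 1 and 2. Within replicates 3 and 4 those comparisons put set 3 against set 2, so ligation and the set cannot be told apart there.

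**Figure D1:**
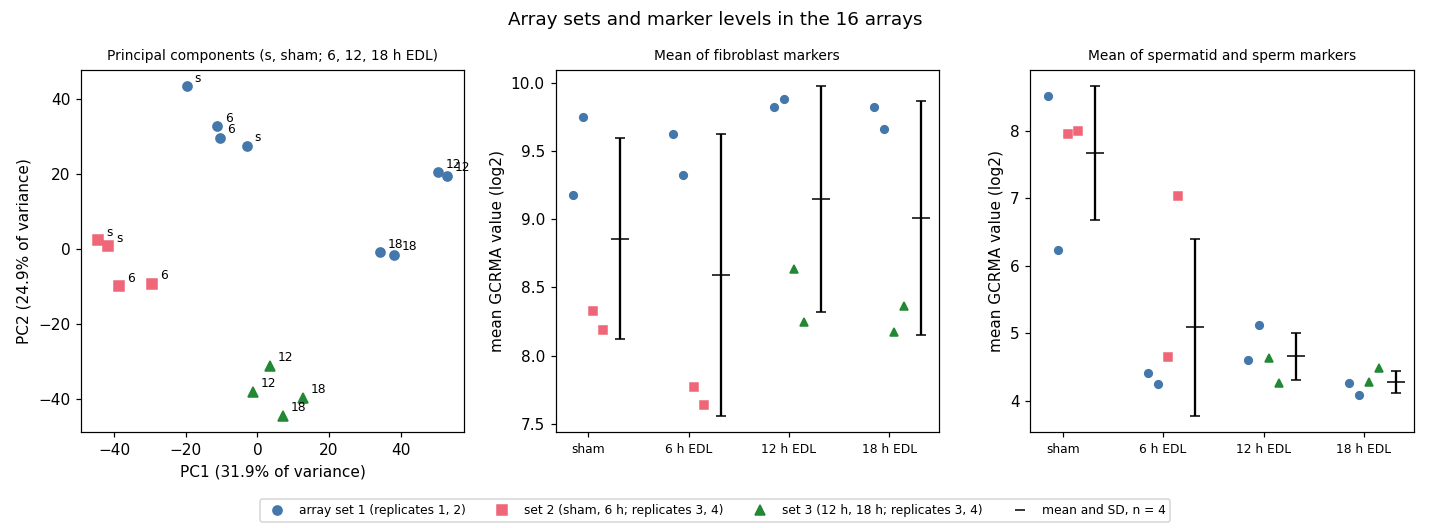
Principal components 1 and 2 (31.9% and 24.9% of the variance), the mean log2 level of the fibroblast markers and that of the spermatid and sperm markers, each point 1 array, coloured by array set. Fibroblast means were 9.18 to 9.88 in set 1 and 7.64 to 8.63 in sets 2 and 3, and sperm marker means were 6.23 to 8.51 in sham and 4.08 to 5.12 in 12 h and 18 h.

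At 6 h, the genes of 2 ERK phosphatases had fallen. Dusp6, which encodes a phosphatase that inactivates ERK in the cytoplasm, fell by 2.70 ± 0.33 (from 10.11 to 7.41; adjusted p = 0.00208; -2.34 and -3.06). Dusp5, which encodes a nuclear ERK phosphatase, fell by 2.50 ± 0.23 (from 10.97 to 8.47; adjusted p = 9.46e-05; -2.61 and -2.39). The fibrinogen chain genes Fgg and Fga, which the liver transcribes in the acute phase response, rose by at least 4.22 ± 0.64 (from 2.90 to 7.12; adjusted p = 0.0143; 3.36 and 5.09) and 3.91 ± 0.56 (adjusted p = 0.0118; 3.17 and 4.65). Another tested probe set of Fga stood at 1.07 and was not called. Sh3tc1 fell by at least 2.78 ± 0.17 (from 6.20 to 3.43; adjusted p = 1.56e-06; -3.08 and -2.47). Further falls were those of Mfsd2a, a lipid transporter (-3.26), Pdgfrl (-2.26), Ppp1r18 (-2.03), Tnfrsf14, a receptor of the TNF receptor family (-1.80), and Nav2 (-1.80). Further rises were those of Cpne8 (1.86), Ampd3, an AMP deaminase (1.48), Rasd1 (1.17), Notch1, a receptor that sets cell fate (1.12), Card14 (1.06), Tcim (0.95; adjusted p = 0.0614 with the replicate block), Gadd45a, a stress-induced growth arrest gene (0.84), and Cited2 (0.81).

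Of the 12 genes tested in the ERK output list (transcripts that ERK signalling keeps up), 2 fell and 10 were not called, with 3 falls adjusted over the list alone and a camera adjusted p of 3.12e-10 (median -0.60, adjusted p = 0.0142 with an estimated correlation and 0.0602 with that and the set block). Etv5, Etv4 and Etv1, transcription factor genes downstream of ERK, stood at -1.37 ± 0.57 (adjusted p = 0.753), -0.56 ± 0.43 and -0.22 ± 0.19, and Spry4, an ERK feedback inhibitor, at -0.06 ± 0.11. Of 13 STAT targets, 1 rose, 5 rose adjusted over the list alone. Camera gave 8.62e-06 (median 0.55, adjusted p = 0.0881 with an estimated correlation). Among 6 spermatid and sperm markers, the sperm mitochondrial gene Smcp fell by 3.99 ± 0.77 (adjusted p = 0.0487, 0.0506 with the set block and 0.0606 with the replicate block), 4 fell adjusted over the list alone. Camera gave 3e-06 (median -3.37, adjusted p = 0.113 with an estimated correlation). Cholesterol synthesis genes were higher as a list (camera 6.79e-06, median 0.30, adjusted p = 0.117 with an estimated correlation), with 3 of 16 higher adjusted over the list alone. The unfolded protein response list was higher (camera 0.00012, adjusted p = 0.474 with an estimated correlation), as was the interferon response list (camera 0.0268, adjusted p = 0.474 with an estimated correlation), while smooth muscle markers were lower (camera 0.00024, median -0.29, adjusted p = 0.346 with an estimated correlation). In these 4 lists limma called 0 members over all probe sets, with 5 of 16, 2 of 19, 2 of 13 and 1 of 10 at an unadjusted p under 0.05. Without sham replicate 2 the interferon list had an adjusted p of 0.0967, and without 6 h replicate 3 of 0.275.

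For NFKB targets limma called 0 of 15 genes (0 at an unadjusted p under 0.05), with a median of -0.01, a mean of 0.04 and a camera direction of down (0.561). Nfkbia, the gene of the NFKB inhibitor, stood at -0.10 ± 0.13. The 12 pro-apoptotic genes had 0 calls (4 at an unadjusted p under 0.05), with 1 higher and 3 lower adjusted over the list alone (median -0.03, mean 0.02, camera down, 0.163), and the 12 anti-apoptotic genes had 0 calls (1 at an unadjusted p under 0.05, camera 0.0515, 0.0395 with the set block and 0.0455 with the replicate block). Bcl2l1, which encodes the survival protein Bcl-xL, had means under 5 in all 4 groups (4.04 in sham, then 3.83, 4.20 and 4.62), so no change is given for it. Socs3, a STAT3 target, did not reach the minimum level. Fibroblast markers had a median of -0.27, 0.02 and -0.51 in the 2 pairs of replicates. Camera gave 0.156, 0.00159 with the set block and 0.00182 with the replicate block. Macrophage markers had a median of -0.18 (camera 0.163, or 0.0395 with the set block), and injury and matrix genes a median of -0.15 (camera 0.0559, 0.0197 with the set block and 0.0103 with the replicate block). With the set block and an estimated correlation, the anti-apoptotic, fibroblast, macrophage and injury lists gave adjusted p = 0.403, 0.403, 0.504 and 0.504.

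Over all tested probe sets, 38 differed between 6 h and sham, 15 higher and 23 lower (14 and 16 genes), with 764 at an unadjusted p under 0.05. The set block gave 54, replicates 1 and 2 alone gave 4, and replicates 3 and 4 alone gave 3. The count was 19 without sham replicate 2, 13 without sham replicate 3, 7 without sham replicate 4, 11 without 6 h replicate 1, 10 without 6 h replicate 2 and 11 without 6 h replicate 3. Of the 19 named calls, Dusp5, Dusp6 and Sh3tc1 held in each of the 8 fits without 1 array. Without sham replicate 4 the adjusted p was 0.0527 for Fga, 0.0512 for Tnfrsf14 and 0.0640 for Fgg, which also missed the threshold without 6 h replicate 2 (0.0508) and 6 h replicate 3 (0.0616). Nav2 missed it without sham replicate 4 (0.0640), 6 h replicate 1 (0.0627) and 6 h replicate 3 (0.0587), and Pdgfrl without sham replicates 3 (0.0510) and 4 (0.0512) and 6 h replicates 1 (0.0552) and 3 (0.0587). The other 11 lost their calls in 5 to 7 of the 8 fits, with the highest adjusted p between 0.0732 (Gadd45a, without 6 h replicate 1) and 0.196 (Smcp, without 6 h replicate 1). The 7 lists called rose to 12 without sham replicate 4, 11 without 6 h replicate 1 and 12 without 6 h replicate 2, and to 11 with the set block.

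**Figure D2:**
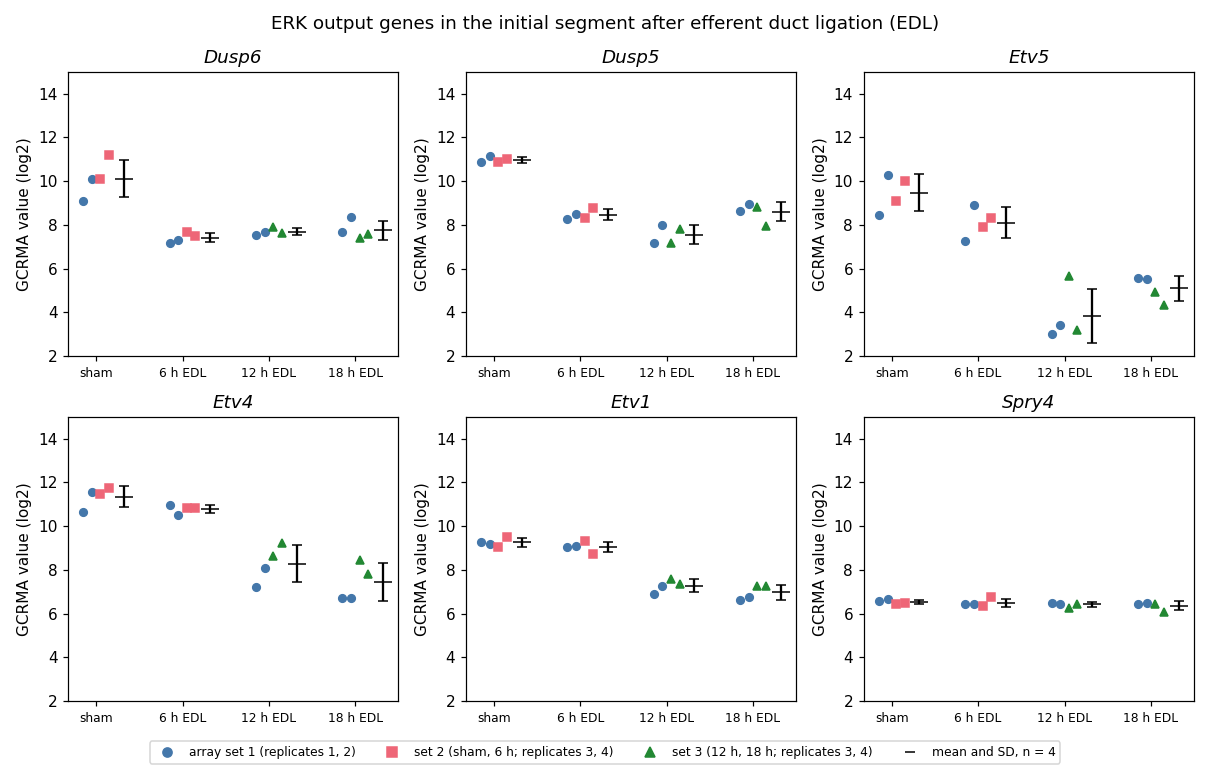
Log2 level of Dusp6, Dusp5, Etv5, Etv4, Etv1 and Spry4 in sham, 6 h, 12 h and 18 h tissue, each point 1 array, with the mean and SD (n = 4). Dusp6 and Dusp5 fell by 6 h, Etv5, Etv4 and Etv1 by 12 h, and Spry4 was called at no time.

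By 12 h the Etv genes had fallen as well. Etv5 fell by 5.64 ± 0.57 (adjusted p = 3.17e-05; -6.15 and -5.13), Etv4 by 3.08 ± 0.43 (adjusted p = 0.000468; -3.46 and -2.69) and Etv1 by 1.99 ± 0.19 (adjusted p = 1.99e-05), and Dusp5 and Dusp6 stood at -3.42 ± 0.23 (adjusted p = 8.16e-07) and -2.42 ± 0.33 (adjusted p = 0.000348). Fgg rose by at least 7.11 ± 0.64 (adjusted p = 1.37e-05; 7.15 and 7.07) and Fga by at least 5.99 ± 0.56 (adjusted p = 1.99e-05). The other tested probe set of Fga stood at 1.66 and was not called (adjusted p = 0.294). Ccl2, which encodes a chemokine that draws monocytes, rose by at least 5.16 ± 0.88 (adjusted p = 0.0022; 6.56 and 3.75), and Mmp7, an epithelial matrix protease gene, by at least 5.25 ± 0.82 (adjusted p = 0.00116; 4.57 and 5.92). B3galt5 (4.12), Nags (3.88) and Rasl10a (2.90) also rose. Pdgfrl fell by 5.37 ± 0.34 (adjusted p = 6.27e-07) and Nkd2, a Wnt pathway inhibitor gene, by 4.58 ± 0.35 (adjusted p = 2.62e-06). Cmahp (-6.08; -7.86 and -4.29), Mogat1, an acylglycerol transferase gene (-5.42), Mfsd2a (-5.25) and Slc52a3, a riboflavin transporter gene (-4.54), fell too.

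In the ERK output list 8 of 12 genes fell and 4 were not called (8 adjusted over the list alone, 6 with the set block). Camera gave 1.12e-08 (median -1.47, adjusted p = 0.0272 with an estimated correlation and 0.0805 with that and the set block). Spry4 stood at -0.13 (adjusted p = 0.629). Of 13 STAT targets 7 rose and 6 were not called (9 adjusted over the list alone, camera 3.54e-07, adjusted p = 0.0388 with an estimated correlation), with Cebpd, an inflammatory transcription factor gene, at 2.47 ± 0.23 (adjusted p = 1.44e-05; 2.86 and 2.07) and Bcl6, a transcriptional repressor gene, at 1.93 ± 0.37 (adjusted p = 0.00495). Of 15 NFKB targets 4 rose (6 adjusted over the list alone, camera 0.000925, adjusted p = 0.287 with an estimated correlation), among them Bcl3 (1.65 ± 0.34), the adhesion molecule gene Icam1 (1.35 ± 0.29, adjusted p = 0.0102; 1.33 and 1.37) and Nfkbia (0.64 ± 0.13, adjusted p = 0.00718). Of 13 interferon response genes 7 rose (10 adjusted over the list alone, camera 2.09e-07, adjusted p = 0.0566 with an estimated correlation), such as the immunoproteasome gene Psmb8 (1.21 ± 0.22) and the GTPase gene Gbp2 (1.12 ± 0.24). Isg15, a ubiquitin-like interferon-induced gene, rose by 2.16 ± 0.52 (adjusted p = 0.0193; 0.0538 without sham replicate 2, 0.0520 without sham replicate 3 and 0.0574 without 12 h replicate 1). Beside these immune lists, the 12 macrophage markers had a median of 0.87 in replicates 1 and 2 and -0.34 in replicates 3 and 4. Limma called 0 of them (1 at an unadjusted p under 0.05). Camera gave 0.576, 0.00425 with the set block (adjusted p = 0.519 with that and an estimated correlation) and 0.00273 without 12 h replicate 4.

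Of 16 immediate early genes, which respond first to growth and stress signals, 5 rose and 1 fell (6 and 1 adjusted over the list alone, camera 0.00363, adjusted p = 0.477 with an estimated correlation), with Myc at 1.85 ± 0.28 (adjusted p = 0.00082) and Egr1 at 1.74 ± 0.32 (adjusted p = 0.00348; 1.87 and 1.61). Of 13 p53 targets 5 rose (5 adjusted over the list alone, camera 0.00928, or 0.0628 with the set block, adjusted p = 0.195 with an estimated correlation). Gadd45a rose by 2.32 ± 0.13 (adjusted p = 2.42e-07) and Gadd45g by 1.66 ± 0.22 (adjusted p = 0.00037), and the cell cycle inhibitor gene Cdkn1a rose by 1.74 ± 0.40 (adjusted p = 0.0155; 0.59 and 2.89; 0.12 with the set block and 0.0546 without sham replicate 4). The pro-apoptotic list had 1 rise and 2 falls among 12 (2 and 3 adjusted over the list alone), with a median of 0.09, a mean of 0.15 and a camera direction of down (0.962). Bcl2l11, which encodes the death activator Bim, rose by 1.39 ± 0.31 (adjusted p = 0.0128), and Bok, of the same family, fell by 0.72 ± 0.11 (adjusted p = 0.00125). The anti-apoptotic list had 1 rise among 12 (3 higher and 1 lower adjusted over the list alone, camera 0.776). That rise was Tnfrsf21 (1.34, adjusted p = 0.0409), a death receptor gene, so it does not stand for a rise of survival genes.

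Among genes of the initial segment, 1 of 12 rose and 1 fell, the same adjusted over the list alone (camera 0.229). With the set block 1 rose and 4 fell and camera gave 0.0122 (adjusted p = 0.436 with that and an estimated correlation), and the median was -0.82 in replicates 1 and 2 and 0.00 in replicates 3 and 4. Ggt1, a gamma-glutamyl transferase gene that luminal factors keep up, fell by 0.60 ± 0.17 (adjusted p = 0.0434; 0.106 without sham replicate 2, 0.131 without sham replicate 3, 0.0955 without sham replicate 4, 0.138 without 12 h replicate 1 and 0.122 without 12 h replicate 2). Cst8, a cystatin gene of the initial segment, stood at -1.18 (adjusted p = 0.254). Of the 6 sperm markers 4 fell, the same 4 adjusted over the list alone (camera 0.000214, median -3.95, -3.09 and -4.67, adjusted p = 0.196 with an estimated correlation), among them Odf1, a sperm tail gene (-5.74 ± 1.02), and the protamine gene Prm1 (-4.05 ± 0.75). Injury and matrix genes had 2 rises among 18 (3 adjusted over the list alone, camera 0.0374, adjusted p = 0.728 with an estimated correlation). Leaving out 1 array ended that list's call in 6 of 8 fits (0.108, 0.0649 and 0.129 without sham replicates 1, 3 and 4, and 0.0650, 0.139 and 0.0659 without 12 h replicates 1, 2 and 3).

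Limma called 1054 probe sets between 12 h and sham, 505 higher and 549 lower (366 and 364 genes), and 764 of them were also called among the 1181 with the set block. The counts were 617 in replicates 1 and 2 (330 higher and 287 lower) and 572 in replicates 3 and 4 (200 higher and 372 lower). With the replicate block the count was 1709, and 182 were called the same way in both pairs of replicates. Without sham replicate 4 the count was 626, and without 12 h replicate 1 it was 675. The 2 pairs of replicates had fold changes that correlated across probe sets with r = 0.574 (probe sets are not independent replicates), and the effect itself differed between them for 6 probe sets.

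**Figure D3:**
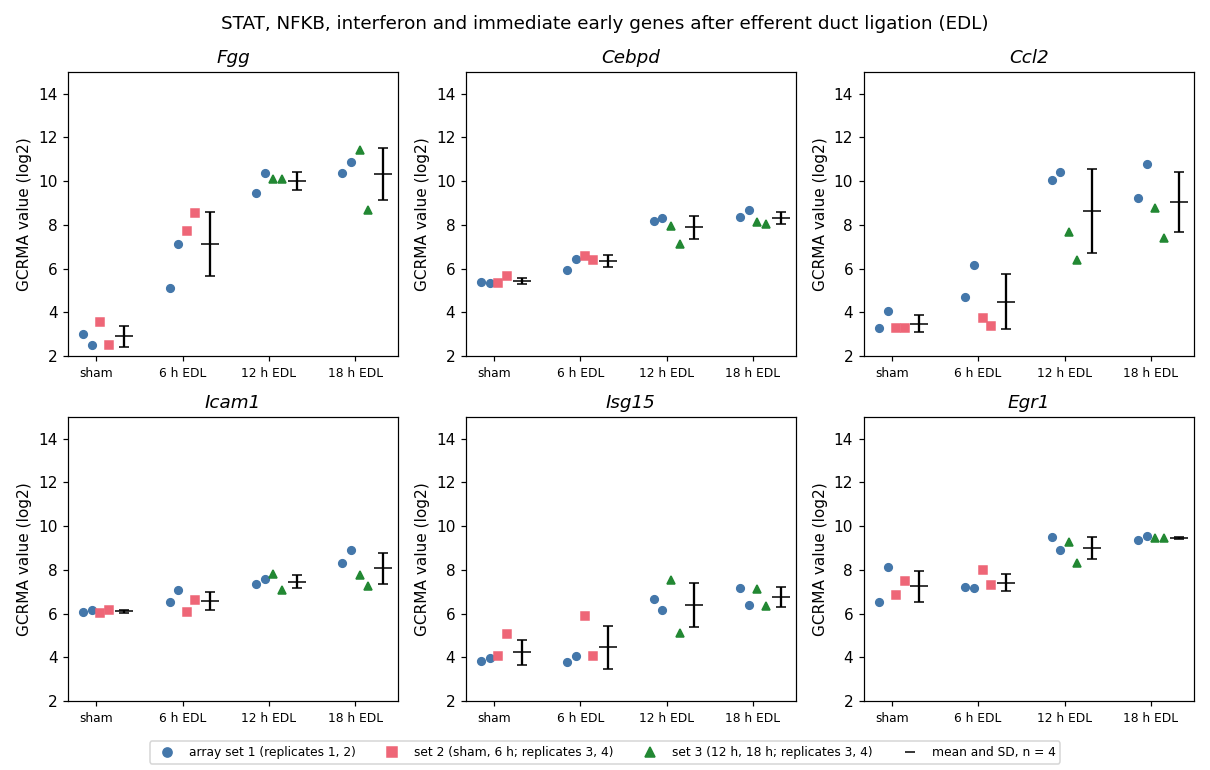
Log2 level of Fgg, Cebpd, Ccl2, Icam1, Isg15 and Egr1 in sham, 6 h, 12 h and 18 h tissue, each point 1 array, with the mean and SD (n = 4). Against sham, only Fgg of these was called at 6 h, and all were called at 12 h and 18 h.

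At 18 h Etv4 fell by 3.92 ± 0.43 (adjusted p = 5.04e-05; -4.37 and -3.47), Etv5 by 4.37 ± 0.57 (adjusted p = 0.000212; -3.83 and -4.90), Dusp5 by 2.37 ± 0.23 (adjusted p = 1.56e-05) and Dusp6 by 2.36 ± 0.33 (adjusted p = 0.000335; -1.57 and -3.14). Fgg rose by at least 7.43 ± 0.64 (adjusted p = 7.4e-06; 7.85 and 7.01), Mmp7 by at least 7.23 ± 0.82 (adjusted p = 6.53e-05; 7.93 and 6.52) and Ccl2 by at least 5.56 ± 0.88 (adjusted p = 0.00093). Krt17, a keratin gene of stressed epithelium, rose by at least 6.47 ± 1.12 (from 2.42 to 8.90; adjusted p = 0.00173; 6.27 and 6.67). Fga (6.86), the cystine transporter gene Slc7a11 (4.55) and the protease inhibitor gene A2m (4.45) rose too, and the stress transcription factor gene Atf3 rose by at least 3.69 ± 0.77 (adjusted p = 0.0067, 0.054 with the set block). The other tested probe set of Fga rose by 3.76 (adjusted p = 0.00937). Odf1 fell by at least 6.29, with all 4 arrays of 18 h at the floor. Other falls were those of Pdgfrl (-5.60 ± 0.34), Mogat1 (-5.59), Nkd2 (-5.26), Mfsd2a (-5.23), Cmahp (-5.07), Slc52a3 (-4.91) and Smcp (-4.63).

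The ERK output list had 1 rise and 6 falls among 12 (1 and 8 adjusted over the list alone, camera 1.27e-06, median -1.14, adjusted p = 0.0467 with an estimated correlation and 0.107 with that and the set block). The rise was Ier3, a stress-induced survival gene (1.21), while Spry4 stood at -0.18 (adjusted p = 0.414). Immediate early genes had 11 rises and 1 fall among 16 (12 and 1 adjusted over the list alone, camera 7.63e-06, adjusted p = 0.155 with an estimated correlation), with Fos at 2.55 ± 0.57 (adjusted p = 0.0105), Egr1 at 2.21 ± 0.32 (adjusted p = 0.000449) and Myc at 2.20 ± 0.28. STAT targets had 7 rises among 13 (8 higher and 1 lower adjusted over the list alone, camera 6.29e-06, adjusted p = 0.0543 with an estimated correlation), with Cebpd at 2.88 ± 0.23 (adjusted p = 3.61e-06; 3.14 and 2.62). Of 15 NFKB targets 7 rose (9 adjusted over the list alone, camera 3.87e-07, adjusted p = 0.0758 with an estimated correlation), such as Icam1 (1.95 ± 0.29), the apoptosis inhibitor gene Birc3 (1.57 ± 0.26) and Nfkbia (0.71 ± 0.13, adjusted p = 0.00263). Of 13 interferon response genes 9 rose (12 adjusted over the list alone, camera 1.07e-10, adjusted p = 0.0424 with an estimated correlation), such as Isg15 (2.53 ± 0.52), Ifit2 (1.94 ± 0.36) and the peptide transporter gene Tap1 (1.92 ± 0.23). Of 12 macrophage markers 1 rose (1 adjusted over the list alone, 3 with the set block). Camera gave 0.163, 0.00012 with the set block (adjusted p = 0.406 with that and an estimated correlation) and 0.0366 without 18 h replicate 4 (median 0.39, 0.63 and 0.16). That marker was Cd14, at 1.92 ± 0.46 (adjusted p = 0.0158; 0.0537 without 18 h replicate 1 and 0.0502 without 18 h replicate 2).

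In the apoptosis lists genes moved both ways. Of 12 pro-apoptotic genes 1 rose and 3 fell (5 and 3 adjusted over the list alone, camera 0.708), with Bcl2l11 at 1.89 ± 0.31 (adjusted p = 0.00126) and the fall of Bok at -0.45 (adjusted p = 0.0227; 0.069 with the set block, 0.0545 and 0.0628 without sham replicates 2 and 4, and 0.0551 without 18 h replicate 4). Of 12 anti-apoptotic genes 4 rose and 1 fell, as when adjusted over the list alone (camera 0.563), and the fall was Bag1, a co-chaperone gene (-0.61 ± 0.13). The death receptor gene Tnfrsf21, which is counted among the 4 rises of the anti-apoptotic list, rose by 2.48 ± 0.37 (adjusted p = 0.000619). Of 13 p53 targets 4 rose (5 adjusted over the list alone, camera 0.13, or 0.0397 without sham replicate 1), among them Cdkn1a (2.42 ± 0.40, adjusted p = 0.00132), Gadd45a (1.61 ± 0.13) and Gadd45g (1.27). The unfolded protein response list had 3 rises among 19 (3 higher and 1 lower adjusted over the list alone), a median of -0.11, a mean of 0.23 and a camera direction of down (0.834).

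Of 12 initial segment genes 1 rose and 1 fell (2 and 1 adjusted over the list alone, camera 0.598). Ggt1 fell by 0.76 ± 0.17 (adjusted p = 0.00941), and Cst8 stood at -0.49 (adjusted p = 0.682). The 7 genes of the more distal caput had 1 rise (1 adjusted over the list alone, camera 0.802). Injury and matrix genes had 4 rises among 18 (6 adjusted over the list alone, camera 0.00131, adjusted p = 0.47 with an estimated correlation), and epithelial markers 4 among 13 (7 higher and 1 lower adjusted over the list alone, camera 0.0185, 0.0649 with the set block, adjusted p = 0.0758 with an estimated correlation), led by the epithelial transcription factor gene Elf3 (2.97 ± 0.34, adjusted p = 7.38e-05). Cholesterol synthesis genes had 2 falls among 16, the same adjusted over the list alone (camera 0.0183, 0.0575 with the set block; 0.0617, 0.0580 and 0.0631 without sham replicate 1, sham replicate 3 and 18 h replicate 1, adjusted p = 0.46 with an estimated correlation). Sperm markers had 4 falls among 6, the same adjusted over the list alone (camera 3.55e-05, median -4.33, adjusted p = 0.12 with an estimated correlation). Fibroblast and smooth muscle markers had 0 calls (1 and 0 at an unadjusted p under 0.05, camera 0.834 and 0.802), and endothelial markers had 2 rises among 9 (2 higher and 1 lower adjusted over the list alone, camera 0.425), of which the VEGF receptor gene Kdr rose by 0.95 (adjusted p = 0.00876).

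Limma called 1362 probe sets between 18 h and sham, 697 higher and 665 lower (500 and 427 genes), and 963 of them were also called among the 1357 with the set block. Replicates 1 and 2 gave 828 (483 higher and 345 lower) and replicates 3 and 4 gave 1030 (332 higher and 698 lower). The balance of directions turned between the pairs, but in replicates 3 and 4 this comparison is also one of set 3 with set 2. In both pairs 304 were called the same way, and the fit without sham replicate 4 gave 879. The fold changes of the pairs correlated across probe sets with r = 0.693, and the effect differed between them for 55 probe sets. Of the 89 named genes called at 18 h, 63 kept their call in each of the 8 fits without 1 array, against 51 of 72 at 12 h. The moderated F-test over the 3 times called 1368 probe sets, 2241 with the replicate block.

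**Figure D4:**
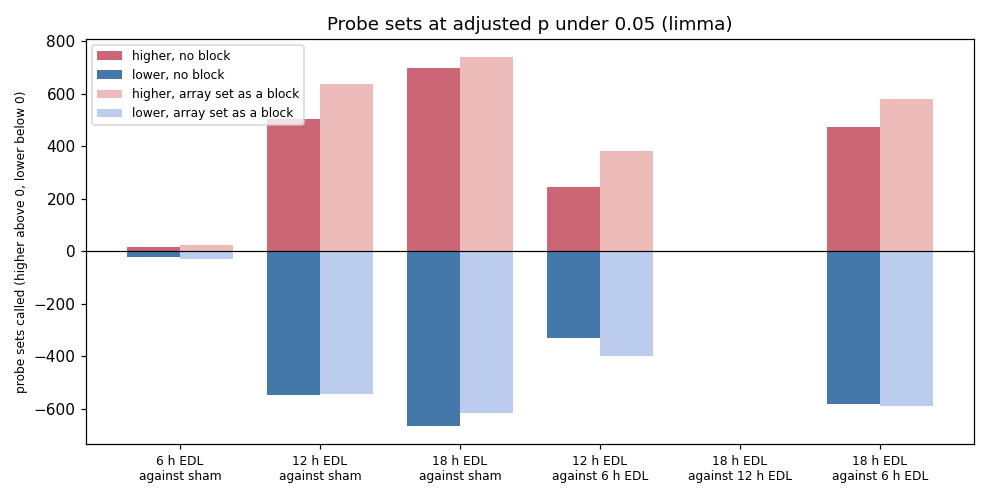
Probe sets called by limma (adjusted p under 0.05) in 6 comparisons, higher above 0 and lower below 0, without a block and with the array set as a block (n = 4 arrays per group). The counts without and with the set block were 38 and 54 at 6 h, 1054 and 1181 at 12 h, and 1362 and 1357 at 18 h against sham.

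The comparison of 12 h with 6 h, both ligated, asked what came on between those times. Etv5 fell by 4.27 ± 0.57 (adjusted p = 0.000935; -4.87 and -3.68), Etv4 by 2.51 ± 0.43 (adjusted p = 0.00497) and Etv1 by 1.77 ± 0.19 (adjusted p = 0.000156), while Dusp6 stood at 0.28 ± 0.33 (adjusted p = 0.751). Cebpd rose by 1.56 ± 0.23 (adjusted p = 0.00152), Nfkbia by 0.74 (adjusted p = 0.00597), Psmb8 by 1.38 (adjusted p = 0.00343), Myc by 1.57 (adjusted p = 0.00599) and Gadd45a by 1.49 (adjusted p = 3.77e-05). Mmp7 (4.62), Nags (3.70) and B3galt5 (3.41) rose, and Cmahp (-6.25) and Slc52a3 (-4.58) fell. Egr1 rose by 1.57 (adjusted p = 0.0134, 0.0504 without 12 h replicate 1), and Ccl2 by 4.15 ± 0.88 (adjusted p = 0.0171; 0.0612 without 6 h replicate 3, 0.0626 without 12 h replicate 1 and 0.0516 without 12 h replicate 2). Ggt1 was not called (-0.62, adjusted p = 0.0517), but was with the set block (0.021), with the replicate block (0.017) and without 12 h replicates 3 (0.0343) and 4 (0.0371).

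Between these times 4 of 12 ERK output genes fell (1 higher and 5 lower adjusted over the list alone, camera 0.00444, adjusted p = 0.233 with an estimated correlation). Immediate early genes had 5 rises among 16 (6 adjusted over the list alone, camera 0.000258, adjusted p = 0.252 with an estimated correlation). Rises among STAT, NFKB, interferon and p53 targets numbered 3, 2, 4 and 3 (4, 6, 5 and 5 adjusted over the list alone). Camera gave 0.00101, 3.52e-05, 3.52e-05 and 0.00312 (each adjusted p = 0.203 with an estimated correlation). Injury and matrix genes had 2 rises (3 adjusted over the list alone, camera 8.26e-05, adjusted p = 0.287 with an estimated correlation), and smooth muscle markers were higher as a list (camera 0.00468, median 0.37, adjusted p = 0.323 with an estimated correlation) with 0 of 10 called by limma (3 at an unadjusted p under 0.05). Initial segment genes were lower as a list (camera 0.00949; -0.93 and -0.08; 0.0549 without 12 h replicate 2, adjusted p = 0.309 with an estimated correlation), with 0 of 12 called by limma (8 at an unadjusted p under 0.05), 3 lower adjusted over the list alone and 4 with the set block. The unfolded protein response list had 1 fall (camera 0.0258; 0.0514 with the set block, 0.165 without 6 h replicate 3 and 0.512 without 12 h replicate 2, adjusted p = 0.67 with an estimated correlation). Fat markers had 1 rise (camera 0.0258; 0.109 without 12 h replicate 2, adjusted p = 0.233 with an estimated correlation). Macrophage markers were not called, with a median of 0.42 (0.99 and -0.05) and a camera adjusted p of 0.0559, but gave 1.37e-05 with the set block and 0.0164 with the replicate block. Fibroblast markers gave 0.131, 0.00135 with the set block and 0.000898 with the replicate block. Each gave adjusted p = 0.352 with the set block and an estimated correlation.

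Limma called 574 probe sets between 12 h and 6 h, 244 higher and 330 lower (173 and 222 genes), 779 with the set block (389 called in both) and 1166 with the replicate block. Replicates 1 and 2 gave 544 (251 higher and 293 lower) and replicates 3 and 4 gave 115 (37 higher and 78 lower), of which 35 were called the same way in both pairs. The count was 323, 309 and 245 without 6 h replicates 1, 2 and 3, and 258 and 350 without 12 h replicates 1 and 2. Of the 43 named calls, 22 held in each fit without 1 array and 21 did not.

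Between 12 h and 18 h no single gene was called, while 5 lists were. Of the 35 ways to split these 8 arrays 4 and 4, 16 called as many lists, so chance cannot be excluded for this count. Cholesterol synthesis genes were lower at 18 h as a list (median -0.39, -0.44 and -0.39, camera 7.76e-10, adjusted p = 0.0779 with an estimated correlation), with 8 of 16 lower adjusted over the list alone. Msmo1, a sterol oxidase gene, stood at -0.57 ± 0.13 (adjusted p = 0.323). Interferon response genes (camera 9.75e-05, median 0.37; 3 adjusted over the list alone, adjusted p = 0.307 with an estimated correlation) and NFKB targets (camera 0.000354, median 0.38; 1 adjusted over the list alone, adjusted p = 0.36 with an estimated correlation) were higher. Immediate early genes (camera 0.000666; 0.12 without 12 h replicate 4; 4 higher and 1 lower adjusted over the list alone, adjusted p = 0.406 with an estimated correlation) and basal cell markers (camera 0.00421; 2 adjusted over the list alone, adjusted p = 0.36 with an estimated correlation) were higher too. Macrophage markers, not called with all arrays (camera 0.318), gave 0.00734 without 12 h replicate 1 and 0.00106 without 12 h replicate 2. Limma called 0 probe sets (877 at an unadjusted p under 0.05), and 0 with the set block, 2 with the replicate block, 110 in replicates 1 and 2 and 1 in replicates 3 and 4. The count was 22 without 12 h replicate 3, 1 without 18 h replicate 3 and 53 without 18 h replicate 4. Krt17 stood at 4.36 ± 1.12 (adjusted p = 0.338; 6.28 and 2.44), and was called without 12 h replicate 3 (2.94e-05). Dusp5 stood at 1.04 ± 0.23 (adjusted p = 0.279, 0.0282 without 18 h replicate 4). The 5 lists called rose to 9 without 12 h replicate 2.

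From 6 h to 18 h, a comparison free of the sham arrays, Etv4 fell by 3.36 ± 0.43 (adjusted p = 0.00041), Etv5 by 3.00 ± 0.57 (adjusted p = 0.00523) and Etv1 by 2.07 (adjusted p = 3.98e-05). Ier3 rose by 1.56 ± 0.30 (adjusted p = 0.00569), and Dusp6 stood at 0.34 (adjusted p = 0.609). Mmp7 (6.60 ± 0.82), Krt17 (6.49 ± 1.12), Fos (2.96), Cebpd (1.98), Icam1 (1.49) and Tap1 (1.30) rose, and Nkd2 (-4.30 ± 0.35), Aqp9, a water and glycerol channel gene (-2.19), and Msmo1 (-0.92 ± 0.13, adjusted p = 0.00119) fell. Of 16 cholesterol synthesis genes 6 fell (10 adjusted over the list alone, camera 4.05e-07, median -0.53, adjusted p = 0.0947 with an estimated correlation). Immediate early, STAT, NFKB and interferon genes had 11, 5, 6 and 8 rises (12, 6, 11 and 11 adjusted over the list alone), with 1 fall each in the first 2 lists. Camera gave 1.96e-07, 0.00291, 4.73e-09 and 2.19e-09 (adjusted p = 0.136, 0.18, 0.085 and 0.0679 with an estimated correlation). Injury and matrix genes had 6 rises among 18 (11 adjusted over the list alone, camera 1.71e-06, adjusted p = 0.224 with an estimated correlation). Macrophage markers, which moved with these lists, had 1 rise among 12 (2 adjusted over the list alone, 6 with the set block). Camera gave 0.0122 (0.0531 without 6 h replicate 3 and 0.0812 without 18 h replicate 2, adjusted p = 0.548 with an estimated correlation). The ERK output list had 1 rise and 3 falls among 12 (2 and 4 adjusted over the list alone, camera 0.177).

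Weaker list calls between 6 h and 18 h were lost when single arrays were left out. Epithelial markers (camera 0.0428, adjusted p = 0.147 with an estimated correlation) had 4 rises, and gave 0.117 with the set block, 0.0829 with the replicate block, 0.0638 and 0.0616 without 6 h replicates 3 and 4, and 0.0710 and 0.0563 without 18 h replicates 2 and 3. Smooth muscle markers (camera 0.0204, adjusted p = 0.498 with an estimated correlation) had 1 rise, and gave 0.0978 and 0.0616 without 6 h replicates 3 and 4, and 0.0507 and 0.0579 without 18 h replicates 2 and 4. The unfolded protein response list (camera 0.0369, adjusted p = 0.548 with an estimated correlation) had 2 falls, and gave 0.055 with the set block, 0.0702 with the replicate block, 0.135 without 6 h replicate 3, and 0.0880 and 0.152 without 18 h replicates 1 and 4. Fat markers (camera 0.0428, adjusted p = 0.237 with an estimated correlation) had 1 rise, and gave 0.0515 with the replicate block, 0.0757, 0.0531 and 0.0546 without 6 h replicates 2, 3 and 4, and 0.125 and 0.110 without 18 h replicates 1 and 2. Fibroblast markers were not called (camera 0.237), but gave 0.0312 with the set block (adjusted p = 0.506 with that and an estimated correlation) and 0.0185 with the replicate block. Limma called 1057 probe sets, 475 higher and 582 lower (362 and 360 genes), 1173 with the set block (748 in both) and 1927 with the replicate block. Replicates 1 and 2 gave 621 (333 higher and 288 lower), replicates 3 and 4 gave 460 (135 higher and 325 lower), and 128 were called the same way in both pairs. The count was 686 without 6 h replicate 1 and 661 without 6 h replicate 3, and 43 of the 73 named calls held in each fit without 1 array, and the 11 lists called fell to 6 without 6 h replicate 3 and 7 without 18 h replicate 2.

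The 3 comparisons against sham share the sham arrays, so their overlap was set against simulated unchanged groups and against split sham arrays. Simulated arrays varied independently and splits did not all balance replicates 1 and 2 with 3 and 4, so these comparison values leave the divide between the replicates out of account. At 12 h and 18 h 343 probe sets rose and 426 fell at both times, none in opposite directions, against 26.2 and 27.2 for independent lists and 0 for simulated groups. With the sham arrays split, the overlap was 273 to 334 over 6 splits. The covariance of the fold changes was 0.276, against 0.0433 simulated (a difference of 0.233) and 0.200 to 0.259 with split sham arrays, and their correlation of 0.853 stood against 0.496 simulated and 0.502 to 0.772 split. At 6 h and 12 h 15 rose and 22 fell at both times (0.565 and 0.942 for independent lists, 0 simulated; 5 to 20 split), and the covariance was 0.0760, against 0.0431 simulated and -0.0158 to 0.0776 split. Their correlation of 0.468 lay below the 0.492 of simulated unchanged groups (-0.0618 to 0.442 split). At 6 h and 18 h 13 rose, 22 fell and 1 went in opposite directions (0.780 and 1.14 for independent lists, 0 simulated; 5 to 17 split), and the covariance was 0.0726, against 0.0438 simulated and -0.00532 to 0.0632 split. The correlation of 0.422 also lay below the simulated 0.499 (-0.0206 to 0.327 split).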

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

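Of the tests on patterns given here, those on the share of non-epithelial tissue, on the array set for sperm transcripts and both on the cystatins and Penk were chosen after the result was seen. The others were written down before their results.

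Among 101 named genes, levels in ligated tissue differed between times for 65, by limma's test of the difference itself. With 1 sham group for all 3 times, these differences cannot be told from changes with time apart from ligation. In all 96 differences were called, 35 between 12 h and 6 h, 61 between 18 h and 6 h, and 0 between 18 h and 12 h. These genes were named in part because they were called, so the share is not that of all genes, and over all 13410 probe sets 4.28% were called between 12 h and 6 h and 7.88% between 18 h and 6 h. Leaving out 1 array ended 21 of the 43 calls that the rule for naming genes took between 12 h and 6 h, and 30 of the 73 between 18 h and 6 h. Where 2 log2 values follow a gene, the first is the difference of 12 h from 6 h and the second that of 18 h from 6 h. The named genes are given by direction, and other members of their lists did not all follow. The ETS factor genes Etv5 (-4.27 and -2.997), Etv4 (-2.51 and -3.36) and Etv1 (-1.77 and -2.07) were lower, and Dusp5 was lower at 12 h (-0.92), while Dusp6, another gene of the ERK output list, was not called (0.28 and 0.34). Other genes lower at both times were Pdgfrl (-3.12 and -3.34), Nkd2 (-3.62 and -4.30), Fgf1 (-1.82 and -1.75), Mogat1 (-3.31 and -3.48), Slc52a3 (-4.58 and -4.95), Slc1a1 (-1.50 and -1.42), Aqp9 (-1.39 and -2.19), Ggt5 (-1.38 and -2.38), Cmahp (-6.25 and -5.24), Krt79 (-4.79 and -4.79) and Bag1 (-0.55 and -0.85). Lower at 12 h were Tnfrsf14 (-1.40), Gpr155 (-4.68) and Per2 (-0.90). Lower at 18 h were Ggt1 (-0.79), Egln3 (-1.46), Msmo1 (-0.92), Fdft1 (-0.78), Idi1 (-0.66) and Sc5d (-0.65).

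Higher than at 6 h at both later times were Myc (1.57 and 1.93), Egr1 (1.57 and 2.04), Fgg (2.89 and 3.21), Ccl2 (4.15 and 4.55), Cebpd (1.56 and 1.98), Nfkbia (0.74 and 0.81), Isg15 (1.93 and 2.30) and Psmb8 (1.38 and 1.25). So were Gadd45a (1.49 and 0.77), Cdkn1a (1.74 and 2.42), Mmp7 (4.62 and 6.60), Lgals3 (0.87 and 0.96), Card14 (0.88 and 1.03), Nags (3.70 and 3.24), B3galt5 (3.41 and 1.65), Rasl10a (2.49 and 1.73) and Wfdc10a (1.57 and 1.51). Higher at 18 h were Fos (2.96), Atf3 (3.59), Ier3 (1.56), Fga (2.95), A2m (2.50), Bcl3 (1.67), Icam1 (1.49), Birc3 (1.58), Gbp2 (1.21), Ifit2 (1.38), Tap1 (1.30) and Tnfrsf21 (1.47). Also higher at 18 h were Krt17 (6.49), Krt7 (2.21), Elf3 (1.43), Anxa1 (0.86), Anxa2 (0.93), Actg2 (0.73), Kdr (0.85), Plvap (1.17), Cd68 (1.52), Slc7a11 (3.03), Trpv6 (1.30) and Cpne8 (1.26).

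In 43 of 400 groups of 4 arrays (10.8%), 1 array stood apart from the other 3 by Dixon's test, and chance gives about 1 in 20 groups. The test divides the gap by the group's own range, so a gap of hundredths of a log2 unit can pass it, as for Socs3 at 6 h (SD 0.0105) and for B3galt5 and Rasl10a in sham (SD 0.0368 and 0.0329). The log2 values of these arrays were as follows in immune and acute phase genes: Fga (2.93 in sham replicate 4), A2m (3.89 in sham replicate 4), Ccl2 (4.06 in sham replicate 2), Nfkbia (8.58 in 18 h replicate 1), Isg15 (5.90 in 6 h replicate 3), Ifit2 (3.71 in 6 h replicate 4), Cd68 (3.35 in 6 h replicate 3) and Socs3 (2.26 in 6 h replicate 1). In ERK and early response genes they were Etv5 (5.66 in 12 h replicate 3), Spry4 (6.08 in 18 h replicate 4), Egr1 (7.99 in 6 h replicate 3) and Atf3 (6.90 in 12 h replicate 3). In genes of death and stress they were Bok (9.23 in sham replicate 3), Dapk1 (9.35 in 18 h replicate 3), Chac1 (3.92 in sham replicate 1) and Mt2A (10.35 in 18 h replicate 4). In epithelial, endothelial and transport genes they were Krt7 (6.61 in sham replicate 2), Krt79 (4.79 in sham replicate 1 and 5.002 in 18 h replicate 3), Kdr (7.81 in sham replicate 2), Plvap (4.57 in sham replicate 1), Aqp9 (12.07 in sham replicate 1 and 12.38 in 6 h replicate 1), Mfsd2a (5.80 in sham replicate 1 and 2.51 in 18 h replicate 3) and Slc52a3 (6.75 in sham replicate 1). In genes of metabolism and the clock they were Nags (5.18 in 12 h replicate 3), B3galt5 (2.63 in sham replicate 4), Cmahp (9.13 in sham replicate 1), Fdft1 (8.60 in sham replicate 2) and Per2 (7.15 in 6 h replicate 4). In the remaining genes they were Cpne8 (6.44 in 18 h replicate 4), Tcim (10.90 in 18 h replicate 4), Sh3tc1 (3.29 in 12 h replicate 1), Nav2 (6.62 in 6 h replicate 2), Rasl10a (3.96 in sham replicate 4) and Gpr155 (8.94 in sham replicate 1), and in cystatin genes Cst8 (13.03 in 18 h replicate 3) and Cst12 (11.63 in sham replicate 1). In sperm genes they were Smcp (6.22 in 6 h replicate 4), Odf1 (7.87 in 6 h replicate 4 and 4.40 in 12 h replicate 2) and Oaz3 (5.97 in 6 h replicate 4).

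A control outside the groups' comparisons marked array set 2: the bacterial dap transcript was at 7.10 and 7.41 in sham replicates 3 and 4 and at 7.93 and 7.88 in 6 h replicates 3 and 4, against the floor of 2.22 in the other 12 arrays.

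Replicates 1 and 2 stood apart from replicates 3 and 4 in all 4 groups. If labelling or hybridisation chemistry acting on single probe sets were a cause, a gene's probe sets would often part, and 67.7% of the other probe sets of the genes that differed went the same way (614 of 907), against 97.8% (313 of 320) for the 18 h effect (Fisher's exact test, two-sided, p = 3.65e-35), which is consistent with it. Among differences under 1 log2 unit the shares were 66.1% and 96.7% (Fisher's exact test, p = 2.82e-24), among those of 1 to 2 they were 88.9% and 100% (p = 0.00433 by the same exact test), and among those of 2 or more all 6 and all 30 went the same way. A smaller share of all non-epithelial tissue in replicates 3 and 4 would lower the markers of every such cell type alike, but fibroblast markers lay 1.36 further down than endothelial ones (a difference of medians of -1.36, permutation p = 0.00081), which argues against it. The permutation takes marker genes as independent, and endothelial markers, at array means of 6.07 to 6.82, lay nearer the background. Smooth muscle markers, at 8.94 to 9.93, had a median of -0.24, while macrophage markers had -0.89. A difference in single cell types, such as fibroblasts and macrophages, stays open, and no biological explanation was tested, because no group of the design divides the replicates.

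Sperm and spermatid transcripts were lower after ligation, at arrays' means of 6.23 to 8.51 in sham and 4.08 to 5.12 at 12 h and 18 h, and 1 of the 6 h arrays, replicate 4, was at 7.04. The array set alone does not account for this, because the median change at 18 h was -3.86 within replicates 1 and 2, all of set 1. It was -4.54 in replicates 3 and 4, where sham and 18 h lie in different sets. In both pairs 5 of 6 genes were lower. If 1 source of these transcripts varied in share between pieces of tissue, they would deviate from their group means together, and their mean pairwise correlation was 0.430, against a median of 0.00177 and a 95th percentile of 0.240 over 1000 random sets, which is consistent with such a source. Less sperm entering the duct after ligation, which the design names, and sperm washed out of the tissue in dissection both remain open, as neither was tested apart.

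Penk, Cst8, Cst11 and Cst12, genes expressed in the initial segment, had 12 h changes against sham in replicates 1 and 2 of -3.19, -1.97, -1.14 and -2.64, against -0.01, -0.38, -0.12 and 0.02 in replicates 3 and 4. The effect differed between the pairs for Penk (adjusted p = 0.0276) but was not called to differ for Cst8 (0.257), Cst11 (0.174) or Cst12 (0.158), and over all 4 arrays none was called (adjusted p = 0.200, 0.254, 0.186 and 0.334 in the same order). The array set would put the 4 genes lower in replicates 1 and 2 at every time. The median difference between the pairs was 0.05 (0.0509, SD 0.217) at 18 h (Penk 0.22), against -2.92 (SD 1.04) at 12 h (Penk -3.49). This argues against a set effect alike at both times. The genes were picked for a 12 h pattern after their values were seen, so the test cannot exclude the array set as a cause. The test as first written, on sham, gave -0.50 (SD 0.322), at its bound, and decided nothing. Pieces taken further along the duct could lower these genes and raise those of the more distal caput, whose median at 12 h in replicates 1 and 2 was 0.278 (SD 1.23 over 7 genes, 5 of them higher). That spread leaves this explanation open, along with a biological difference between the replicates, which was not tested.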

How the results depend on the processing

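The blocks for array sets and for replicates 1 and 2 against 3 and 4, and the fits within these pairs, were chosen after seeing the data. Each alternative changed 1 choice. Counts of called probe sets stayed within 1.5 times those reported (38, 1054 and 1362 at 6, 12 and 18 h against sham) with a trend and robust prior (40, 1072 and 1370), centred arrays (37, 1041 and 1338), quantile normalization (38, 1035 and 1366), cyclic loess (34, 1053 and 1358) and the 3 array sets as a block (54, 1181 and 1357). Averaging by symbol called 26, 777 and 989. These are genes, and probe sets with several symbols or none are left out, so they are not like counts. Apart from the fits without 1 array, single named genes gave 5972 results, 5267 on the same side of the threshold in the same direction, 615 weaker, 90 stronger and 0 reversed. Lists gave 2964, of which 2766 were the same, 102 weaker, 95 stronger and 1 reversed. The fits without 1 array gave 3472 more results for named genes, 2931 the same, 525 weaker, 16 stronger and 0 reversed. For lists they gave 1488 more, 1410 the same, 34 weaker, 44 stronger and 0 reversed. In each array 31.2% to 33.0% of probe sets lay at the floor, where no fall can be measured, and of simulated changes of 0.5 log2 units only 17.9% were recovered. A small change that was not called is therefore no evidence of no change.

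Values outside these limits follow by alternative, and the cause was not tested except where given. With no minimum level, more than 2 times as many probe sets were tested (31042), which makes the adjustment stricter, and 7 were called at 6 h, 653 at 12 h, 277 for 12 h against 6 h, 642 for 18 h against 6 h and 904 by the F-test. With only the groups compared in the fit there were fewer arrays for the spread, and 15, 477 and 827 were called at 6, 12 and 18 h and 323 for 12 h against 6 h. A fold change of at least 2, stricter by construction, left 25, 481 and 602 against sham, 260 for 12 h and 446 for 18 h against 6 h. An adjusted p under 0.01, also stricter, left 6, 440 and 638, then 162 and 439 in the same order, and 658 by the F-test. With arrayWeights 104, 2426 and 2111 were called, 1471 for 12 h against 6 h, 56 for 18 h against 12 h and 2653 by the F-test. Split sham arrays (fewer arrays per comparison) left 320, 334, 273, 303, 278 and 309 probe sets called alike at 12 h and 18 h, against 769.

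With the replicate number as a block 1709 were called at 12 h, 2165 at 18 h, 1166 for 12 h against 6 h, 2 for 18 h against 12 h, 1927 for 18 h against 6 h and 2241 by the F-test. The lowest correlation between 18 h and sham arrays of the same number was 0.00651, so at 18 h the number was not taken to pair the arrays. Over all groups the closest array of another group had the same number in 28 of 48 cases and came from the same pair of replicates in 48. Besides the changes given in the report, this block ended the 12 h calls of Hlf (adjusted p = 0.0553) and Sqle (0.0532). It added Gusb at 12 h (0.0407), Pdgfra at 18 h (0.0298), Ube2c (0.0378), Cldn4 (0.0168), Col3a1 (0.00783) and Gusb (0.0407) for 12 h against 6 h, and Tnfrsf1a (0.0414) and Hook1 (0.0397) for 18 h against 6 h, and it changed no other call of a named gene or list. Replicates 1 and 2 against 3 and 4 as a block gave 1735 at 12 h, 2179 at 18 h, 1215 for 12 h against 6 h, 2 for 18 h against 12 h, 2030 for 18 h against 6 h and 2393 by the F-test.

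Within replicates 1 and 2 alone 4, 617 and 828 were called against sham, 110 for 18 h against 12 h, 621 for 18 h against 6 h and 865 by the F-test. Within replicates 3 and 4 alone 3 were called at 6 h, 572 at 12 h, 115 for 12 h against 6 h, 1 for 18 h against 12 h, 460 for 18 h against 6 h and 565 by the F-test. Both fits rest on fewer arrays. For 18 h against 12 h the smooth muscle list, not called over all arrays (camera adjusted p = 0.985), was called in the opposite direction, higher at 18 h, within replicates 3 and 4 (adjusted p = 0.00205).

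Leaving out each array in turn gave 7 to 48 probe sets at 6 h, 626 to 1079 at 12 h, 879 to 1371 at 18 h, 245 to 608 for 12 h against 6 h, 0 to 53 for 18 h against 12 h, 661 to 1159 for 18 h against 6 h and 1025 to 1496 by the F-test. Called lists numbered 7 to 12, 7 to 9, 8 to 10, 8 to 14, 4 to 9 and 6 to 12 in the 6 comparisons in the same order. Of the list calls reported (7, 8, 9, 11, 5 and 11), an estimated correlation, which widens the null, left 1, 2, 2, 0, 0 and 0. Fry, which asks whether a list moved at all, called 4 lists at 6 h and 1 for 18 h against 12 h. At 6 h a stricter minimum level gave 11 called lists, and the array sets as a block 11.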

Other observations

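The tests over all splits of the arrays were written down before their results, and those over splits balanced between the pairs of replicates, the splits that part each pair and the test of a difference between the pairs were chosen after the arrays were seen to divide along the replicate numbers.

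Transport and metabolism held single large changes inside lists that camera did not call against sham with all arrays in the fit. Of 15 tested genes for ion, water and acid-base transport 1 rose and 2 fell at 12 h, and the same numbers at 18 h (1 and 2 adjusted over the list alone at both times), where camera gave adjusted p = 0.118 and 0.332. The water and glycerol channel Aqp9 fell by 1.42 ± 0.22 at 12 h (adjusted p = 0.00116) and by 2.23 ± 0.22 at 18 h (adjusted p = 2.34e-05), and the glutamate carrier Slc1a1 by 1.83 ± 0.22 (0.000148) and 1.75 ± 0.22 (0.000142). At 6 h limma called 0 of these genes (0 at unadjusted p < 0.05), and camera gave 0.128 (0.0406 without sham replicate 4). Of 23 glutathione and oxidative stress genes 0 were called at 6 h (1 at unadjusted p < 0.05) and 1 fell at 12 h, and 4 rose and 4 fell at 18 h (5 and 4 adjusted over the list alone, camera adjusted p = 0.708). The glutathione peroxidase Gpx2 rose by at least 3.69 ± 0.76 (adjusted p = 0.00639) and the gamma-glutamyltransferase Ggt5 fell by 2.30 ± 0.36 (adjusted p = 0.00079). Of 20 hypoxia and glycolysis genes 2 rose and 2 fell at 12 h (3 and 4 over the list alone), and 1 rose and 3 fell at 18 h (3 and 4), with camera at 0.787 and 0.563. The prolyl hydroxylase Egln3 fell by 2.45 ± 0.32 (adjusted p = 0.000304) and 2.78 ± 0.32 (7.59e-05). At 6 h 0 were called by limma (3 at unadjusted p < 0.05) and camera gave 0.113, but 0.0487 without sham replicate 3 and 0.0156 and 0.0365 without 6 h replicates 1 and 2.

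Lists of growth factors, hormone targets and the clock also held single called genes. Of 20 growth factors and receptors 0 were called at 6 h by limma (2 at unadjusted p < 0.05), 1 rose and 2 fell at 12 h, and 3 fell at 18 h (3 up and 4 down over the list alone), with camera at adjusted p = 0.626, 0.873 and 0.834. Fgf1 fell by 2.38 ± 0.30 at 12 h (adjusted p = 0.000214) and 2.31 ± 0.30 at 18 h (0.000195). Of 13 androgen and glucocorticoid targets 0 were called at 6 h (1 at unadjusted p < 0.05), 1 rose and 1 fell at 12 h, and 2 rose and 1 fell at 18 h, with camera at 0.314, 0.438 and 0.398. Mt2A rose by 2.22 ± 0.30 at 12 h (adjusted p = 0.000391) and by 2.16 at 18 h (0.000387). Of 15 clock genes 0 were called at 6 h (2 at unadjusted p < 0.05), and 2 rose and 3 fell at 12 h and again at 18 h, with camera at 0.470, 0.576 and 0.531. Bhlhe41 rose by 1.36 at 12 h (adjusted p = 0.0041) and 1.63 at 18 h (0.000825). Of 9 cell cycle genes 0 were called at 6 h (0 at unadjusted p < 0.05), 1 rose and 1 fell at 12 h and 1 fell at 18 h, with camera at 0.314, 0.962 and 0.664. Of 8 reference genes limma called 0 at 6 h (0 at unadjusted p < 0.05), 0 at 12 h (1 at unadjusted p < 0.05) and 1 at 18 h, where Gusb fell by 0.41. Among the cell types at 18 h, 2 of 8 basal cell markers rose and 1 fell (camera adjusted p = 0.398), 0 of 5 narrow and clear cell markers (0 at unadjusted p < 0.05, camera 0.747) and 0 of 4 T and B cell markers (1 at unadjusted p < 0.05, camera 0.864) were called by limma, and 1 of 5 fat markers, Gpd1, rose by 1.05. Markers of efferent duct ciliated cells (1 tested), mast cells (1), blood (2) and neutrophils (0) were too few for a test.

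To see whether chance can be excluded, each comparison was refitted over the 35 ways to split its 8 arrays 4 and 4. For probe sets 1 split, the real one, reached the count at 12 h (1054, highest other 926), at 18 h (1362, highest other 2) and for 18 h against 6 h (1057, highest other 51), and 1 of 100 drawn splits reached that of the F-test (1368, highest other 10), so chance can be excluded there over free splits of the arrays, which take no account of pairing or of the divide between replicates. At 6 h 2 splits reached the count (38, highest other 116), as they did for 12 h against 6 h (574, highest other 982), so chance cannot be excluded there by this count. For 18 h against 12 h the real count was 0, which all 35 splits reach whatever the data, so nothing can be said of chance there (highest other 1867). The highest other split divided replicates 1 and 2 from replicates 3 and 4 in each comparison of 8 arrays except that of 18 h with sham, where this split gave 1, and at 6 h it called several times the real count, which points to a structure of the samples, as do the 1867 calls it gave between 18 h and 12 h. The 18 splits balanced over the divide are too few for a share under 0.05. Among these splits, which keep 2 arrays of each pair of replicates on each side, the real one alone reached the count at 6 h, 12 h and 18 h and for 12 h and 18 h against 6 h, with the highest other at 0 or 1. For 18 h against 12 h the highest of these was 285. With the replicate number as a block, the 8 splits that part each pair are too few for a share under 0.05. The real counts there were 46 at 6 h, 1709 at 12 h, 1166 for 12 h against 6 h, 2 for 18 h against 12 h and 1927 for 18 h against 6 h, each with the highest other at 0. For gene lists 13 of 35 splits called as many as at 6 h (7, highest other 10), 5 as at 12 h (8, highest other 11), 5 as at 18 h (9, highest other 11), 4 as for 12 h against 6 h (11, highest other 13), 16 as for 18 h against 12 h (5, highest other 10) and 4 as for 18 h against 6 h (11, highest other 13), so chance cannot be excluded for any count of lists.

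Limma's test of whether the effect of ligation differed between the pairs of replicates called 0 probe sets at 6 h (605 at unadjusted p < 0.05), 6 at 12 h, 55 at 18 h, 5 for 12 h against 6 h, 2 for 18 h against 12 h and 7 for 18 h against 6 h. This test rests on 2 arrays per group in each pair of replicates.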
